A study of Homo sapiens with 15 samples.

How the data were processed

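The data were gene expression profiles of Caco-2 cells, a human colon carcinoma line that takes on features of small-intestinal enterocytes when kept at confluence. The 15 samples were labelled as 3 groups of 5: untreated control cells, cells exposed to lipopolysaccharide (LPS, the endotoxin of Gram-negative bacteria) from E. coli at 1 µg/mL for 48 h, and cells given 50 µM trans-resveratrol (RSV, a plant polyphenol) 1 h before the same LPS exposure. Per the labels' protocols, experiments were run between 15 and 19 days after seeding, and 300 ng of total RNA per sample was converted to sense-strand cDNA, fragmented, labelled with biotin and hybridised to an Affymetrix whole-transcript array. The labels do not say which array belonged to which day, nor whether the LPS group received the ethanol in which resveratrol was dissolved. They number the replicates without saying that each came from a separate culture, so p-values measure the spread between these samples, which may be technical.

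The deposited values were log2 expression values, 1 per array and probe set, made with RMA (background correction, quantile normalization and probe summarisation) per the submitters' processing notes; the version was not given in the sources used here. The table held 53617 rows for 15 arrays. Gene symbols came from the platform annotation, which can be old: 16098 rows had 1 symbol, 0 had several and 37519 were unnamed here. The 16098 named rows covered 14884 symbols. The genome build of the array annotation was not given in the sources used here, so no coordinates are printed.

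Values were used on the log2 scale as deposited, with no pseudocount. Each symbol was represented by its brightest probe set, the one with the highest mean over the 15 arrays. Genes were kept if they lay above the 40th percentile of all rows of an array in at least 5 of the 15 arrays, which left 11804 genes. A linear model with 3 group means was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, neither trended nor robust), so that the groups shared 1 estimate of spread per gene. The 3 comparisons were LPS against control, LPS+RSV against LPS, and LPS+RSV against control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11804 genes of a comparison. Adjusted p-values of genes are limma's throughout.

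The 29 gene lists were fixed by hand, and the 24 with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over 72 tests. Antigen presentation, Paneth cell markers, and fibroblast and immune markers had 2, 3 and 4 tested members and were left untested, and 0 mitochondrially encoded genes and 0 replication-dependent histones were named here. Calls were also made with a correlation estimated per list, and with fry, which tests whether the genes of a list move on balance in 1 direction without setting them against other genes. A list score per array was the mean over members of the log2 deviation from the gene's mean over all arrays, and scores were compared with an exact permutation test over all 252 divisions of 10 arrays, whose smallest 2-sided p is 0.00794. Counts given as adjusted over the list alone used the limma p-values of that list's members only.

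The genes named in the text followed a rule: up to 10 called genes of largest change in each direction, or the 5 of lowest p in each direction where none was called; up to 4 called members of each called list; up to 10 genes called with opposite sign in LPS against control and in LPS+RSV against LPS; and 16 genes of endotoxin sensing, lipid metabolism and known resveratrol responses whether or not they passed. Of these 16, LY96 and CXCL8 lay below the filter, CYP1A1 and ALPI had no probe set named here, and 1 is not reported here. Groups, comparisons, gene lists, this rule and the alternatives below, except where stated, were chosen before the data were examined. The scripts were tested on simulated data for 11804 genes, drawn with each gene's own mean and residual spread but with noise independent between genes, unlike the real arrays. In the simulation of LPS against control, 62.7% of genes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2 were recovered, with 8 false calls. In that of LPS+RSV against LPS the recoveries were 79.1%, 100% and 100%, with 9 false calls.

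Alternatives covered the filter, the probe sets per gene, 3 further normalizations, moderation, array weights, a fit to only the 2 groups compared, the replicate number as a block, and each array left out in turn. For gene lists they covered the estimated correlation and fry. Added after the data were seen were the cell cycle score or the first component of the within-group deviations as a covariate, a fit without LPS replicates 1 and 2, and the exact permutation test of list scores. Array medians lay between 5.49 and 5.54, and the number of arrays and the spread between them limit the precision, with a median standard error of 0.098 for a log2 difference between groups.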

Results

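Whole-transcript expression was measured on 15 arrays of Caco-2 cells, 5 each of untreated control cells, cells exposed to LPS for 48 h, and cells pretreated with trans-resveratrol before LPS (LPS+RSV). Over the 11804 genes tested, pairs of arrays correlated between 0.922 and 0.994 across genes. Groups accounted for 24.1% of the variance, and the first component of the deviations from the group means took 45.4% of the variance within groups. Groups without any effect also take part of the variance, and the 24.1% was not set against such a value. LPS+RSV replicate 1 stood apart with a mean correlation of 0.946 with the other arrays, and LPS replicates 1 and 2 stood apart on the third principal component, at 17.8 and 19.4. Control replicates 1 and 2 also lay close together, at -18.5 and -18.2 on the first principal component and -5.43 and -5.54 on the third. The labels do not say whether such pairs shared a culture. If they did, tests that treat arrays as independent, permutation tests included, give p-values that are too small. Arrays of 1 group differed in proliferation genes: the cell cycle score ranged from -0.95 to 0.46 in control, from -0.02 to 0.91 in LPS and from -0.82 to 0.45 in LPS+RSV.

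**Figure D1:**
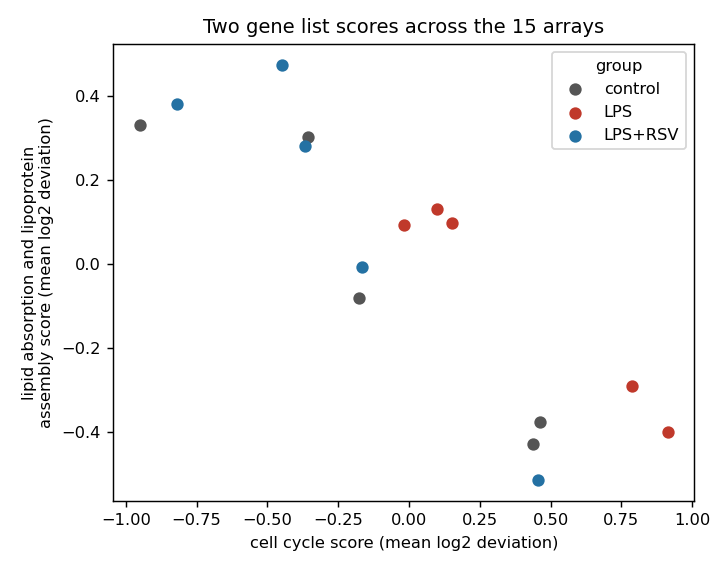
Cell cycle score (horizontal axis) against the score of lipid absorption and lipoprotein assembly genes (vertical axis), both as mean log2 deviation, with 1 point per array and colours for the 3 groups of 5. Arrays of each group ran from upper left to lower right, but not along 1 common line. LPS replicate 4 stood at 0.79 and -0.29, with both scores above those of control replicate 1 at 0.46 and -0.38. The 5 arrays with the highest cell cycle scores, at 0.44 or more, were control replicates 1 and 2, LPS replicates 4 and 5 and LPS+RSV replicate 2.

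The comparison of LPS with control asked how exposure to endotoxin altered enterocyte-like cells. NOX1, which encodes a superoxide-producing NADPH oxidase of the colon epithelium, rose 4.08-fold, from 6.78 ± 0.16 in control to 8.81 ± 0.73 in LPS (log2, mean ± SD, n = 5 arrays each). ETV4, an ETS transcription factor induced by ERK signalling, rose from 6.62 ± 0.27 to 7.52 ± 0.18, and KRT18, a keratin of simple epithelia, from 9.82 ± 0.21 to 10.55 ± 0.12. By camera, genes of the immediate early and MAPK response were higher as a list, and metallothioneins, small metal-binding proteins, were lower; with an estimated correlation each list had an adjusted p = 0.152 and was not called.

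The log2 change of NOX1 was 2.03 ± 0.25 (SE, adjusted p = 0.0047, limma), with a 95% confidence interval of 1.51 to 2.55. The model shares 1 spread over groups whose SDs were 0.73 in LPS, 0.16 in control and 0.15 in LPS+RSV. This SE and interval may therefore be too narrow. The changes of ETV4 and KRT18 were 0.89 ± 0.14 and 0.73 ± 0.11 (adjusted p = 0.038 for each, limma). For these 3 genes all 5 LPS arrays lay above all 5 control arrays. KRT18 has many pseudogenes that can share its probes and is uncertain for that reason; its other probe set differed by 0.34. These were the only genes called, 3 higher and 0 lower, with 930 genes at an unadjusted limma p under 0.05 (545 higher, 385 lower) where chance gives 590. All 5 arrays of 1 group lay beyond all 5 of the other for 2.21% of genes, against 0.794% by chance. NOX1 passed in each of the 10 fits that left out 1 array of these groups, with adjusted p between 0.000157 and 0.0267 in limma. ETV4 passed only without LPS replicate 3 or control replicate 1, and KRT18 only without LPS replicate 3 or control replicate 2; without any 1 of the other arrays of these groups the limma adjusted p was over 0.05 and at most 0.189, and a fit to these 2 groups alone gave 0.0616 for all 3 genes.

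**Figure D2:**
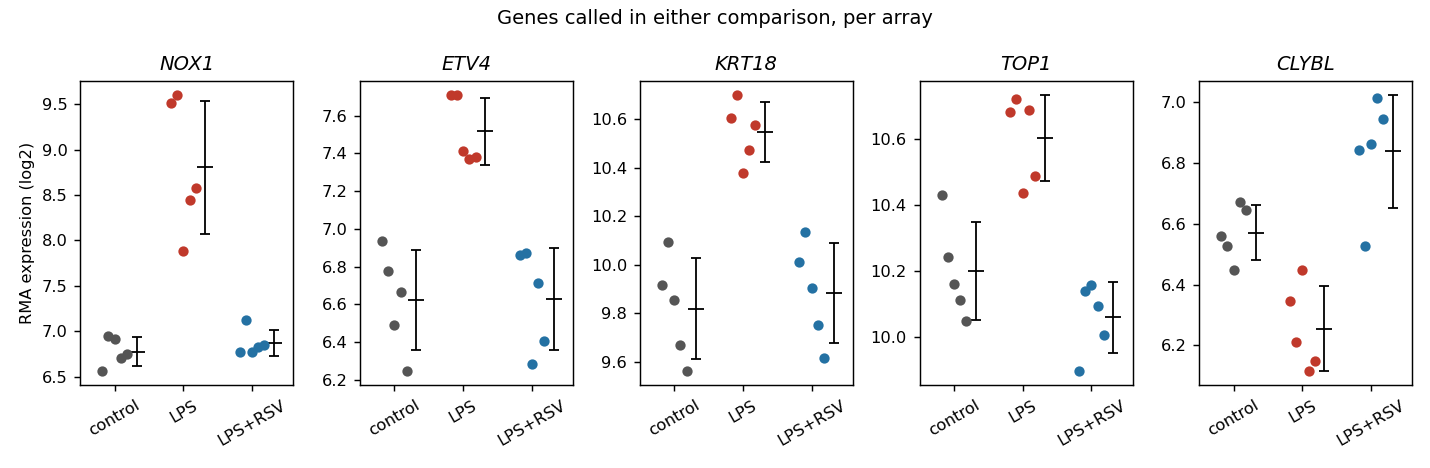
RMA expression (log2, vertical axes with separate scales) of the 5 genes called in either comparison, with 1 point per array and the mean ± SD beside each group of 5. NOX1 lay between 7.89 and 9.60 in LPS and did not exceed 6.95 in control or 7.13 in LPS+RSV.

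Of 24 tested members of the immediate early and MAPK list, 23 were higher in LPS, with a median log2 change of 0.24 (camera adjusted p = 1.02e-11). Adjusted over the list alone 6 rose, against 1, ETV4, over all genes. Examples chosen after their values were seen were DUSP6, an ERK phosphatase, at 1.28 ± 0.28, EGR1 at 0.88 ± 0.26, MYC at 0.87 ± 0.20 and IER3 at 0.59 ± 0.11. With an estimated correlation the list had a camera adjusted p = 0.152, while fry gave an adjusted p = 0.0305. Of 5 metallothionein list members, the 4 metallothionein genes were lower and their regulator MTF1 differed by 0.02, for a median of -0.56 (camera adjusted p = 0.000177), and 3 fell when adjusted over the list alone: MT2A at -0.72 ± 0.18, MT1X at -0.65 ± 0.16 and MT1F at -0.56 ± 0.17, with 0 over all genes. The metallothionein adjusted p was 0.152 in camera with an estimated correlation and 0.0305 in fry. In exact permutation tests of the list scores, the MAPK list had p = 0.00794, the smallest such a test can give, and metallothioneins had p = 0.0159, with Benjamini-Hochberg values of 0.0953 and 0.127. The TGF beta and extracellular matrix list also had an exact permutation p = 0.00794 (Benjamini-Hochberg 0.0953), here and in LPS+RSV against LPS. Camera did not call it (adjusted p = 0.256 and 0.283). LPS replicates 1 and 2, which stood apart, had MAPK scores of 0.34 and 0.40 against 0.09 to 0.12 in the other LPS arrays; without them the score difference from control went from 0.36 ± 0.08 to 0.25 ± 0.05 and the camera adjusted p was 8.47e-06. For metallothioneins these 2 arrays had scores of -0.45 and -0.48 against -0.39 to -0.03, and without them the camera adjusted p was 0.0103.

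All 41 tested cell cycle genes were higher in LPS, with a median of 0.44 (camera adjusted p = 1.02e-11), yet 0 passed limma adjusted over the list alone and 10 had an unadjusted p under 0.05. The members moved together between arrays of 1 group: with an estimated correlation of 0.912 the camera adjusted p = 0.604, and the exact permutation p of the score was 0.175. Cholesterol synthesis and uptake genes were higher for 15 of 17 (median 0.16, camera adjusted p = 3.83e-05), and the prenyl transferase gene FDPS rose by 0.34 when adjusted over the list alone. Hypoxia and glycolysis genes were higher for 13 of 14 (median 0.18, camera adjusted p = 6.21e-05), where EPAS1 at 0.54, HK2 at 0.40 and HK1 at 0.35 passed over the list alone. LPS replicates 1 and 2 had the highest hypoxia scores of their group, 0.22 and 0.32 against -0.10 to 0.18, and the score difference from control was 0.21 ± 0.11 with them and 0.10 ± 0.11 without them. They were also highest for cholesterol genes, where the difference was 0.18 ± 0.09 with them and 0.11 ± 0.09 without them, and in both lists the camera adjusted p without them was 0.0387. Genes of the unfolded protein response and ATF4 were higher for 15 of 17 (median 0.12, camera adjusted p = 0.00537), with STC2 at 0.48 passing over the list alone. With an estimated correlation the camera adjusted p = 0.582 for cholesterol genes, 0.582 for hypoxia and 0.423 for the unfolded protein response. Cytosolic ribosomal protein genes were lower for 20 of 23 (median -0.04, camera adjusted p = 0.0215, and adjusted p = 0.388 with an estimated correlation). That camera call was lost without LPS replicate 1 (0.0613) or 2 (0.0668) or without control replicate 1 (0.0808) or 2 (0.0624), each an adjusted p, and without both LPS replicates 1 and 2 (adjusted p = 0.238).

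Lipid synthesis was the subject named in the series title. Of 25 fatty acid and triglyceride synthesis genes, 19 were higher in LPS, with a median of 0.13 (camera adjusted p = 0.00799, and adjusted p = 0.604 with an estimated correlation). None passed limma adjusted over the list alone (0 genes), and 8 had an unadjusted p under 0.05; without LPS replicate 1 the camera adjusted p was 0.0903. LPS replicates 1 and 2 had scores of 0.19 and 0.16 against -0.05 to 0.00 in the other LPS arrays, and without both the difference from control went from 0.11 ± 0.05 to 0.04 ± 0.03 and the camera adjusted p was 0.577. FASN, the fatty acid synthase, differed by 0.33 ± 0.11 (adjusted p = 0.372, limma), the desaturase SCD by 0.28 ± 0.12 and the lipogenic transcription factor SREBF1 by 0.13 ± 0.06, and none of these passed. The other SCD probe set, dimmer at a mean of 7.75 against 12.72, differed by 0.43. The TLR4 and NF-κB list was higher for 19 of 28 genes, with a median of 0.04 (camera adjusted p = 0.326), and 0 members passed limma over the list alone, with 1 at an unadjusted p under 0.05. The exact permutation p of its score was 0.0238 (Benjamini-Hochberg 0.143), and 7 of the 24 lists had such a p under 0.05 in LPS against control. Its named members did not pass: the chemokine CCL20 differed by 0.61 ± 0.32, the LPS coreceptor CD14 by 0.14 ± 0.09 and the LPS receptor TLR4 by -0.07 ± 0.11. Other fixed genes did not pass either: HMOX1 at 0.16 ± 0.15, SIRT1 at 0.04 ± 0.10, CPT1A at -0.05 ± 0.18, PPARA at -0.06 ± 0.13 and APOA4 at -0.40 ± 0.71.

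The comparison of LPS+RSV with LPS asked what resveratrol pretreatment changed in endotoxin-exposed cells. NOX1 was lower in LPS+RSV, at 6.87 ± 0.15 against 8.81 ± 0.73 (log2, mean ± SD, n = 5 each), and ETV4 and KRT18 were lower at 6.63 ± 0.27 and 9.88 ± 0.21. TOP1, which encodes DNA topoisomerase I, was lower at 10.06 ± 0.11 against 10.60 ± 0.13, and CLYBL, a mitochondrial enzyme gene, was higher at 6.84 ± 0.19 against 6.25 ± 0.14. By camera, metallothioneins were higher as a list, and cell cycle, cholesterol and immediate early genes were lower. None of these lists was called with an estimated correlation, where camera gave an adjusted p = 0.152 for metallothioneins and 0.604 for each of the others.

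NOX1 changed by -1.94 ± 0.25 (SE, adjusted p = 0.00864, limma), with a 95% confidence interval of -2.46 to -1.41. Since the NOX1 spread was largest in LPS and the model shares 1 spread, this interval too may be too narrow. The log2 changes of ETV4, TOP1 and CLYBL were -0.89 ± 0.14, -0.54 ± 0.08 and 0.58 ± 0.09 (adjusted p = 0.0307 for each, limma), and that of KRT18 was -0.66 ± 0.11 (adjusted p = 0.0474, limma). The other KRT18 probe set differed by -0.25. In these 5 genes the 5 arrays of 1 group all lay beyond those of the other. They were the only calls, 1 higher and 4 lower, with 2195 genes at an unadjusted p under 0.05 in limma (954 higher, 1241 lower) and 73 at an adjusted p under 0.10. NOX1 passed in each of the 10 fits without 1 array, with limma adjusted p between 0.000275 and 0.0493. The other 4 genes passed only without LPS replicate 3 or LPS+RSV replicate 2, fits that called 102 and 121 genes, and each fit without 1 of the other 8 arrays called 1 gene. A fit to these 2 groups alone called 0 in limma, with 1897 at an unadjusted p under 0.05.

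All 41 cell cycle genes were lower in LPS+RSV than in LPS, with a median of -0.61 (camera adjusted p = 1.02e-11), but 0 passed limma over the list alone and 22 had an unadjusted p under 0.05. The camera adjusted p = 0.604 with an estimated correlation, and the exact permutation p of the score was 0.0635. Metallothionein list members were higher for 5 of 5, with a median of 0.63 (camera adjusted p = 0.000756), and MT2A at 0.89 ± 0.18, MT1X at 0.84 ± 0.16 and MT1F at 0.63 ± 0.17 rose when adjusted over the list alone. Their adjusted p was 0.152 in camera with an estimated correlation and 0.00761 in fry, and the exact permutation p of the score was 0.00794. Cytosolic ribosomal protein genes were higher for 19 of 23, with a median of only 0.08 (camera adjusted p = 0.00252, adjusted p = 0.152 with an estimated correlation, and fry adjusted p = 0.00264). LPS+RSV replicate 1, which stood apart, had the highest scores of its group for ribosomal genes, at 0.0837 against 0.0198 to 0.0285, and for metallothioneins, at 0.35 against 0.14 to 0.20. Without it the camera adjusted p was 0.000527 and 0.000772.

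Of 17 cholesterol synthesis and uptake genes, 14 were lower (median -0.20, camera adjusted p = 0.00202), and adjusted over the list alone 6 fell, against 0 over all genes. They included the squalene epoxidase gene SQLE at -0.43 ± 0.12, HMGCS1 at -0.38 ± 0.14, FDPS at -0.35 ± 0.10 and the sterol feedback gene INSIG1 at -0.43 ± 0.16. Immediate early and MAPK genes were lower for 16 of 24 (median -0.09, camera adjusted p = 0.00202); 7 fell over the list alone, among them DUSP6 at -0.99 ± 0.28, EREG at -0.97 ± 0.24, MYC at -0.81 ± 0.20 and IER3 at -0.49 ± 0.11. Mitochondrial biogenesis and sirtuin genes were higher for 12 of 14 (median 0.15, camera adjusted p = 0.00537); the mitochondrial deacetylase gene SIRT3 rose by 0.33 over the list alone, whereas SIRT1 differed by -0.24 ± 0.10 (limma adjusted p = 0.223). Fatty acid oxidation and PPARα targets were higher for 12 of 14 (median 0.17, camera adjusted p = 0.0373), with 0 passing limma over the list alone and 4 at an unadjusted p under 0.05. With an estimated correlation, camera adjusted p = 0.604 for cholesterol and for immediate early genes, 0.502 for mitochondrial genes and 0.621 for fatty acid oxidation. Without LPS replicates 1 and 2, which had the highest LPS scores of both lists, the camera adjusted p was 0.103 for cholesterol and 0.14 for immediate early genes, so that neither was called. The score differences went from -0.20 ± 0.07 to -0.13 ± 0.07 for cholesterol and from -0.26 ± 0.09 to -0.15 ± 0.06 for immediate early genes. LPS+RSV replicate 1 had the highest scores of its group for mitochondrial genes (0.21 against -0.01 to 0.11), fatty acid oxidation (0.40 against -0.19 to 0.18) and immediate early genes (0.13 against -0.18 to 0.00). Without it the mitochondrial score difference went from 0.13 ± 0.05 to 0.10 ± 0.04 and the camera adjusted p was 0.0134. The fatty acid oxidation call was lost without LPS replicate 4 (0.065) or 5 (0.0843) and without LPS+RSV replicate 1 (0.173), 4 (0.0813) or 5 (0.0618), as camera adjusted p. Its score difference went from 0.18 ± 0.11 to 0.11 ± 0.10 without LPS+RSV replicate 1. Across the 15 arrays with each group centred, a relation sought after the data were seen, the fatty acid oxidation score ran against the cell cycle score (Pearson r = -0.835, permutation p = 0.001, adjusted p = 0.00329; Spearman rho = -0.882, permutation p = 2e-04, adjusted p = 0.00153). Without the 2 farthest arrays r was -0.773. The mitochondrial score also ran against it (r = -0.624, permutation p = 0.01, adjusted p = 0.0209, rho = -0.764, permutation p = 0.002, adjusted p = 0.00767). There r was -0.604 without the 2 farthest arrays. Without the 5 arrays of highest cell cycle score, r was -0.507 (permutation p = 0.3) and -0.379 (permutation p = 0.4), with rho at -0.648 (p = 0.1) and -0.552 (p = 0.2).

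Fatty acid and triglyceride synthesis genes were lower for 16 of 25 with a median of -0.08 and did not pass as a list (camera adjusted p = 0.295). Adjusted over the list alone 2 genes passed and both were higher: ACACB, an acetyl-CoA carboxylase, at 0.22 ± 0.06 and the desaturase SCD5 at 0.28 ± 0.08. FASN differed by -0.34 ± 0.11 (adjusted p = 0.153, limma), SCD by -0.32 ± 0.12 and SREBF1 by -0.06 ± 0.06. The other, dimmer SCD probe set differed by only -0.14. Between LPS+RSV and control it differed by 0.29, where the one used differed by -0.04. The other fixed genes did not pass either: CCL20 at -0.89 ± 0.32 (limma adjusted p = 0.178), APOA4 at 0.93 ± 0.71, CPT1A at 0.18 ± 0.18, CD14 at 0.12 ± 0.09, TLR4 at 0.06 ± 0.11, PPARA at 0.01 ± 0.13 and HMOX1 at -0.07 ± 0.15. The TLR4 and NF-κB list was lower for 16 of 28 genes with a median of -0.03 (camera adjusted p = 0.759).

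**Figure D3:**
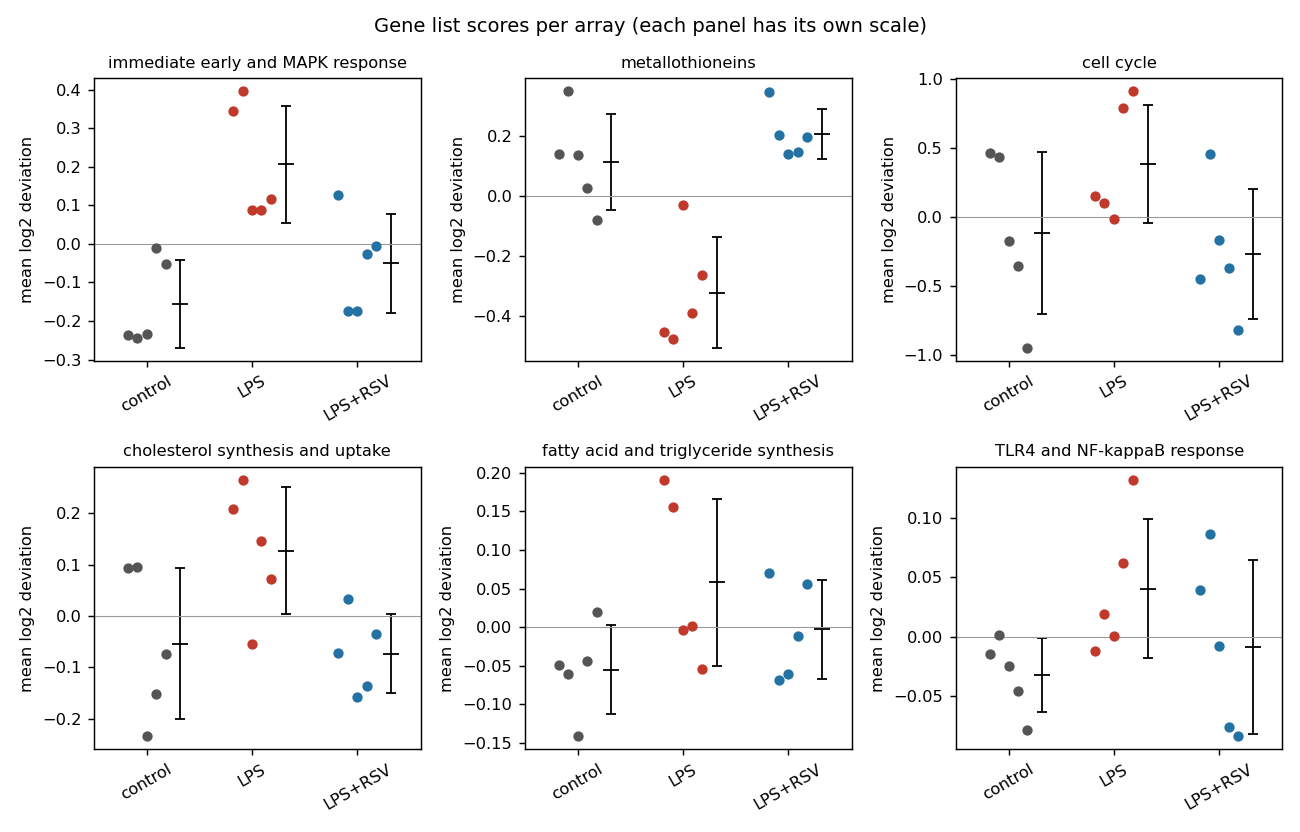
Scores of 6 gene lists (mean log2 deviation, vertical axes with separate scales) in control, LPS and LPS+RSV, with 1 point per array and the mean ± SD beside each group of 5. Metallothionein scores lay between -0.48 and -0.03 in LPS and between 0.14 and 0.35 in LPS+RSV, whereas cell cycle scores of the 3 groups overlapped.

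The comparison of LPS+RSV with control asked how far pretreated, endotoxin-exposed cells differed from untreated ones. No gene was called: limma called 0 genes, with 1239 at an unadjusted p under 0.05 (483 higher, 756 lower) and a smallest adjusted p of 0.464, and the fit to these 2 groups alone also called 0, with 885. Both fits took arrays as unpaired, although 3 of 5 same-numbered pairs deviated together at a correlation over 0.1. Variation shared by such pairs stayed in the spread, so the absence of calls is limited by it. NOX1 differed by 0.09 (95% confidence interval -0.43 to 0.62), ETV4 by 0.01 (-0.29 to 0.30) and KRT18 by 0.06 (-0.17 to 0.30), and the intervals allow differences of these sizes. The NOX1 interval rests on a spread shared with LPS, where the SD was 0.73 against 0.16 in control and 0.15 in LPS+RSV. It may therefore be too wide. The genes of lowest p, none of which passed (limma adjusted p = 0.464), were the antisense transcript SSTR5-AS1 at 0.44, the small RNA SCARNA12 at 0.35, CDRT15L2 at 0.46, CD72 at 0.36 and HEY2 at 0.30, all higher. Those lower were ADAM20P1 at -0.48, DOP1A at -0.41, PSMD6-AS2 at -0.59, TTC33 at -0.43 and ZNF112 at -0.42. Control means of SSTR5-AS1 (5.13), CDRT15L2 (4.83), CD72 (4.80) and HEY2 (5.21) lay below the array medians of all rows (5.49 to 5.54). Camera called 0 of 24 lists, with mitochondrial biogenesis and sirtuin genes closest (11 of 14 higher, median 0.11, adjusted p = 0.071), and fry also called 0. Without LPS+RSV replicate 2 or 3, or without control replicate 4 or 5, camera called 7, 3, 4 and 4 lists. Among the fixed genes CD14 differed by 0.26 ± 0.09 (limma adjusted p = 0.464), SIRT1 by -0.20 ± 0.10, CCL20 by -0.27 ± 0.32 and FASN by -0.01 ± 0.11.

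NOX1, ETV4 and KRT18 were called with opposite sign in LPS against control and in LPS+RSV against LPS, and 0 genes were called with the same sign. KRT18 is uncertain for its pseudogenes, and its other probe set changed less, by 0.34 and -0.25. Independent lists as long as the 3 genes higher in LPS and the 4 lower in LPS+RSV would share 0.00102 genes, a value that leaves out the LPS arrays the comparisons have in common. Across 11804 genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated at -0.64, whereas 100 regroupings of arrays with no group effect gave -0.45 on average and 23 of them were as low. The covariance was -0.0207 (jackknife SE 0.0132) against a simulated mean of -0.0078, a difference of -0.0129. When the LPS arrays were split so that the comparisons shared none, it averaged -0.0137 over 10 splits, and 7 of 100 simulated regroupings were as low.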

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

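In this part, the tests that used the cell cycle score as a covariate, left out LPS replicates 1 and 2 or permuted list scores, and the splits for LPS+RSV against control, were chosen only after the data or the result had been seen. Of 150 checks of groups of 5 arrays, 7 found an array far from the others of its group, and chance alone gives about 5%. NOX1 stood at 7.13 in LPS+RSV replicate 2, against 6.77 to 6.85 in the others of that group. PSMD6-AS2 stood at 5.86 in LPS replicate 3, against 6.12 to 6.19. The tight and adherens junction score of LPS+RSV replicate 1 was 0.114, against -0.05 to -0.02. The hepatocyte and fetal marker score of LPS replicate 3 was 0.497, against -0.10 to 0.02. The TGF beta and extracellular matrix score was -0.0882 in control replicate 5 and -0.132 in LPS+RSV replicate 5, each the lowest of its group. The cytosolic ribosomal protein score of LPS+RSV replicate 1 was 0.0837, against 0.0198 to 0.0285.

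Among probe sets that were unnamed here, and so outside the comparisons, 5 were called in LPS against control by limma. The one of lowest adjusted p has the ID 16912362 and stood at 6.43 ± 0.16 in control, 7.63 ± 0.14 in LPS and 6.75 ± 0.11 in LPS+RSV (log2, mean ± SD, n = 5). It was 1.19 ± 0.09 higher in LPS than in control (limma adjusted p = 3.8e-05 over 33342 rows), with the lowest LPS array at 7.46 and the highest control array at 6.62. It was lower in LPS+RSV than in LPS by a log2 change of -0.88 (limma adjusted p = 0.00246). Over these rows limma called 13 in LPS against control, 8 of them named, and 3 in LPS+RSV against LPS, 1 of them named, where 5 genes were called over the named genes.

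The first pattern is the set of called genes led by NOX1. Fits with the cell cycle score as a covariate kept shares of 0.888 (0.843 to 0.964 without 1 array) of the median change in LPS against control and 0.745 (0.668 to 0.804) in LPS+RSV against LPS. With so few genes each full-set median is that of 1 gene, ETV4 and KRT18. NOX1 went from 2.03 ± 0.25 to 2.04 ± 0.27 and from -1.94 ± 0.25 to -1.95 ± 0.29, which argues against a difference in growth as its whole cause. In LPS+RSV against LPS, ETV4 (-0.89 ± 0.14 to -0.76 ± 0.15), KRT18 (-0.66 ± 0.11 to -0.49 ± 0.10) and TOP1 (-0.54 ± 0.08 to -0.45 ± 0.09) lost their calls as the changes shrank (limma adjusted p = 0.0526, 0.0526 and 0.0519). The score was measured after treatment and its group means differed, so for the other genes these fits do not separate growth from treatment. Arrays that stood apart as the whole cause are argued against too: in LPS against control the share was 0.856 without LPS replicates 1 and 2, where NOX1 was 1.53 ± 0.14 but ETV4 (0.89 ± 0.14 to 0.77 ± 0.16) and KRT18 (0.73 ± 0.11 to 0.66 ± 0.13) lost their calls with fewer arrays (limma adjusted p = 0.536 and 0.486). In LPS+RSV against LPS the share was 1.05 without LPS+RSV replicate 1, where all calls but NOX1 went to limma adjusted p between 0.0656 and 0.0713. There the fit without LPS replicates 1 and 2 called 1 gene, NOX1, and CLYBL, ETV4, KRT18 and TOP1 lost their calls. Of 100 splits of the 10 arrays, 1, the real one, gave as many as 3 genes in LPS against control (highest other 1). In LPS+RSV against LPS, 2 gave as many as 5, the real one included. Such counts were rare among splits, but splits treat arrays as independent cultures, which the labels do not state, so chance between cultures is not excluded. The other split called 493 genes. It kept the treatment groups except that LPS replicate 3 and LPS+RSV replicate 2 changed sides. Its sides correlated at 0.813 with the cell cycle score, so treatment and growth are not separated in it. An effect of LPS that resveratrol pretreatment or its ethanol vehicle prevents may underlie the pattern, but the design does not separate resveratrol from vehicle, and the mean covariance of -0.0137 between the comparisons with LPS arrays split leaves open how much of the opposition across genes came from shared arrays.

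The second pattern is the cell cycle list, higher in LPS and lower in LPS+RSV. Differences between cultures that are not tied to treatment could produce it: the exact permutation p of the score was 0.175 for LPS against control and 0.0635 for LPS+RSV against LPS, and the 5 arrays per group leave this open. LPS+RSV replicate 1 as the whole cause of the difference between LPS+RSV and LPS is argued against by its score. At -0.45 it lay inside the range of the others of its group, -0.82 to 0.45. The score difference was -0.66 ± 0.29 with it and -0.61 ± 0.33 without it. That is a share of 0.932, whose error was too wide for the share alone to decide. For the number of called lists chance cannot be excluded, because 15 of 100 splits gave as many as the 8 of LPS against control (highest other 11) and 13 as many as the 7 of LPS+RSV against LPS (highest other 10). A biological effect of LPS or resveratrol on proliferation stays among the open explanations.

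The third pattern is the metallothionein list, lower in LPS and higher with resveratrol. For the LPS part, LPS replicates 1 and 2 may contribute: the score difference between LPS and control was -0.44 ± 0.11 with them and -0.34 ± 0.13 without them, a share of 0.782 whose error is too wide to decide. As the whole cause of the difference between LPS+RSV and LPS these arrays are argued against by a share of 0.82 (0.53 ± 0.09 with them, 0.43 ± 0.11 without them, where the camera adjusted p was 0.0127). An effect of the treatments on metal-responsive transcription also stays open and was not tested.

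For LPS+RSV against control the real counts were 0 genes in limma (1239 at an unadjusted p under 0.05) and 0 lists in camera and fry. Because all 100 splits reach a count of 0 by construction, the splits decide nothing about chance there. The highest other split called 8 lists, and the highest for genes called 1724, which points to a structure of the samples; its sides correlated at -0.818 with the cell cycle score.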

How the results depend on the processing

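Chosen only after the data were seen were the fits with the cell cycle score or the residual component as a covariate, those without LPS replicates 1 and 2, and the exact permutation of list scores. No called result changed direction in any alternative run; changes of sign were counted only for results called in 1 of the fits. LPS vs control called 3 genes as reported, 15 with array weights, 0 in a fit to only the 2 groups, 6 with the replicate block, 173 with the first residual component as a covariate, 63 with the cell cycle score as a covariate, and 1 to 10 without 1 array, the highest without LPS replicate 3. LPS+RSV vs LPS called 5 genes as reported, 20 after quantile normalization, 12 after cyclic loess, 25 with array weights, 0 in a fit to only the 2 groups, 3 with the replicate block, 1708 with the residual component, 23 with the cell cycle score, 1 without LPS replicates 1 and 2, and 1 to 121 without 1 array. LPS+RSV vs control called 0 genes as reported, 683 with the residual component and 0 to 0 without 1 array. The residual component is balanced over the groups by construction, so that it left log2 changes as they were and lowered only the residual spread; those counts assume that samples did not differ along it by group. Gene lists, LPS vs control, numbered 8 as reported, 0 with estimated correlation, 2 with fry, 0 with the exact permutation and 7 to 10 without 1 array. Gene lists, LPS+RSV vs LPS, numbered 7 as reported, 0, 2 and 0 in these tests and 6 to 8 without 1 array. The exact permutation could hardly call a list in either comparison. Even lists at its smallest possible p, 0.00794, had a Benjamini-Hochberg value of 0.0953. A list could pass only if more lists had reached that p, so these counts of 0 do not show that the camera calls failed. Gene lists, LPS+RSV vs control, numbered 0 as reported and 0 to 7 without 1 array, the highest without LPS+RSV replicate 2. The covariance of the opposition of the LPS and resveratrol effects ranged from -0.031 to -0.0142 without 1 array. The 2-group fits have fewer arrays and so less information on spread. For NOX1, each 2-group fit with LPS also left out a group of small spread (SD 0.15 or 0.16, against 0.73 in LPS). Otherwise the cause was not tested. The replicate numbers did not pair the arrays in every case: same-numbered arrays deviated together at a correlation over 0.1 in 1 of 5 pairs of LPS and control, in 0 of 5 of LPS+RSV and LPS, and in 3 of 5 of LPS+RSV and control (-0.441 to 0.707, highest for replicate 2). Of the arrays, 5 of 15 correlated best with their own number. In cell cycle score, control replicates 2 to 5 stood at 0.44, -0.18, -0.36 and -0.95. LPS+RSV replicates 2 to 5 stood at 0.45, -0.17, -0.37 and -0.82, whereas replicate 1 was at 0.46 in control and -0.45 in LPS+RSV. Same-numbered arrays of control and LPS+RSV thus shared a structure, except for replicate 1. The main model did not pair them, and the replicate block also tied in the LPS arrays, so a paired comparison of these groups was not made. CLYBL and TOP1 were not among the calls with the replicate block, which called 0 genes in LPS+RSV vs control. Under the alternatives chosen beforehand, named genes and lists kept their side of the threshold in 1198 cases and lost it in 96. Genes called in neither fit count as kept, so these numbers do not measure how stable the calls were. Over all alternatives, those chosen later included, NOX1 lost its call in 1 setting per comparison and kept it in 22. TOP1 kept its call in 11 settings and lost it in 12. Signal over background is not known for these values, and genes below the filter were not tested.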

Other observations

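The genes named in this part, the relation between scores and its tests were chosen only after the data were seen. Single members of the junction and AhR lists passed limma adjusted over the list alone, while neither list was called by camera in any comparison (lowest adjusted p = 0.0958 for junctions and 0.287 for AhR targets, both in LPS against control). Adjusted over the list alone in limma, 3 of 19 tight and adherens junction genes rose with LPS: the pore-forming claudin CLDN2 at 0.46 ± 0.11, the desmoglein DSG2 at 0.60 ± 0.19 and the plakophilin PKP2 at 0.31 ± 0.10. In LPS+RSV against LPS, CLDN1 at -0.31 ± 0.08, DSG2 at -0.71 ± 0.19 and PKP2 at -0.44 ± 0.10 fell over the list alone, while CLDN3 at 0.47 ± 0.14 and CLDN15 at 0.31 ± 0.09 rose. LPS replicates 1 and 2 had junction scores of 0.17 and 0.19 against -0.07 to 0.03 in the other LPS arrays. Without them CLDN2 at 0.41 ± 0.14, DSG2 at 0.23 ± 0.13 and PKP2 at 0.21 ± 0.10 did not pass over the list alone in LPS against control (limma adjusted p = 0.111, 0.333 and 0.333). In LPS+RSV against LPS, CLDN1 and PKP2 still passed without them, whereas DSG2 at -0.34 ± 0.13, CLDN3 at 0.44 ± 0.17 and CLDN15 at 0.27 ± 0.10 did not (limma adjusted p = 0.0869 for each). AHR, the aryl hydrocarbon receptor gene, rose by 0.30 ± 0.10 with LPS and changed by -0.49 ± 0.10 with resveratrol over its list of 5 tested genes; without these 2 arrays only the second change passed (limma adjusted p = 0.167 and 0.0159 over the list). NFE2L2, which encodes the antioxidant regulator NRF2, changed by -0.58 ± 0.12 in LPS+RSV against LPS over its list of 13. None of these genes passed limma over all genes.

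Across the 15 arrays, with each group centred, the cell cycle score ran against the score of lipid absorption and lipoprotein assembly genes (Pearson r = -0.93, permutation p = 2e-04, Spearman rho = -0.907, permutation p = 2e-04, adjusted p = 0.00153 for both over 23 lists). Leaving out the 2 arrays farthest from the median gave r = -0.922. Without the 5 arrays of highest cell cycle score, r over the other 10 arrays was -0.689 with a permutation p = 0.1 (rho = -0.588, p = 0.2). Setting these arrays aside also narrows the range of the score and leaves fewer arrays. It therefore cannot decide whether a relation rests on them, here or for the lists below. Inside the groups of 5 arrays r was -0.937 in control, -0.985 in LPS and -0.928 in LPS+RSV. Brush border genes ran the same way (r = -0.878, permutation p = 6e-04, adjusted p = 0.00322; rho = -0.771, permutation p = 0.003, adjusted p = 0.00986). Stem cell and Wnt markers ran with the cell cycle (r = 0.925, permutation p = 1e-04, the smallest 10000 permutations can give; rho = 0.893, permutation p = 2e-04; adjusted p = 0.00153 for both). Over the 10 arrays r was -0.438 (permutation p = 0.3) for brush border genes and 0.811 (permutation p = 0.04) for stem cell markers, with rho at -0.358 (p = 0.3) and 0.648 (p = 0.1). Of the lists called in LPS against control, hypoxia (r = -0.755, permutation p = 0.004, adjusted p = 0.0115, rho = -0.746, permutation p = 0.004, adjusted p = 0.0102) and immediate early genes (r = -0.641, permutation p = 0.02, adjusted p = 0.0329, rho = -0.621, permutation p = 0.02, adjusted p = 0.0383) ran against the cell cycle score within groups. All 3 lists were higher in LPS. Without the 2 farthest arrays r was -0.727 and -0.581, and over the 10 arrays it was -0.524 (permutation p = 0.3) and -0.284 (permutation p = 0.4), with rho at -0.418 (p = 0.3) and -0.2 (p = 0.6). The unfolded protein response ran with the cell cycle (r = 0.727, permutation p = 0.008, adjusted p = 0.0184, rho = 0.636, permutation p = 0.03, adjusted p = 0.0493). It had r = 0.601 without the 2 farthest arrays, and r = 0.183 (permutation p = 0.7) and rho = 0.127 (p = 0.7) over the 10. Fatty acid and triglyceride synthesis had r = -0.568 (permutation p = 0.03, adjusted p = 0.0431, r = -0.472 without the 2 farthest arrays) and rho = -0.557 (permutation p = 0.04, adjusted p = 0.0613), and over the 10 arrays r = -0.502 (permutation p = 0.2) and rho = -0.479 (p = 0.2). Whether a technical factor underlies the r of -0.93 cannot be decided from it, since normalization had already removed a factor that raises all genes alike (array medians 5.49 to 5.54) and factors that move gene groups apart were not tested. The relation was not particular to enterocyte lists. Heat shock (r = 0.817) and TLR4 and NF-κB genes (r = 0.788) ran with the cell cycle score, and AhR targets (r = -0.831) against it. Enteroendocrine markers (r = -0.0254) and ribosomal protein genes (r = 0.2) showed little relation. A hypothesis is that samples differed in maturity, as Caco-2 cells leave the cell cycle while they gain enterocyte functions. The span of 15 to 19 days after seeding may be a source, but the day of each array was not given. The breadth of the relation does not single out maturity.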
